A study of Mus musculus with 12 samples.

How the data were processed

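RNA was extracted from the whole small intestine of 12 C57BL/6 mice, and 1 RNA-seq library was made per mouse, per the labels. The mice were labelled wild type (WT), heterozygous (HET) or knockout (KO) for Zip4, whose gene symbol is Slc39a4 and whose product imports zinc across the apical membrane of the enterocyte. The zinc in the diet was bound in an organic complex through either the amino or the hydroxy end. The 3 genotypes and 2 complexes gave 6 groups of 2 libraries each, assigned from the sample labels. The labels name no shared litter, cage, batch or day, and replicate numbers only name libraries. In HET the labelled ages pair replicates, which the main model ignores. The p-values of single genes and of the exact permutation tests rest on the spread between these animals. Those of the list test camera compare the genes of a list with the other genes, at a preset correlation. The Fisher test counts genes. Neither of these 2 measures the spread between animals. Sample labels give 15 ppm zinc for the WT and HET diets and 40 ppm for the KO diets, while the description of the whole series gives 15 ppm for all. Where the sample labels hold, genotype and zinc level change together in every comparison of KO with WT or HET. The HET mice were 141, 143, 338 and 363 days old, the WT mice 210 to 237 days and the KO mice 198 to 240 days.

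The authors deposited 1 table of CPM values (read counts scaled to the size of the library) for 17112 genes, with 0.0001 added to every value. The submitters' processing notes name Partek, TopHat2 and the mouse build mm10, with neither versions nor the role of each. The counting tool, the annotation and any filter on genes are not given in the sources used here, and whether strand was used is not given either. A gene that shares reads with a paralog, a pseudogene or an overlapping gene is therefore uncertain. The listed genes summed to 62.0% to 71.8% of the library total. Low values rose in steps whose size gave 26.0 to 38.8 M reads per library (median 31.9 M), of which 17.2 to 26.2 M fell in listed genes. At these depths 3 reads correspond to 0.0773 to 0.115 CPM, a limit that covers counting error only. Between 93.4% and 94.5% of the values of a library lay within 0.05 of a whole number of reads. The other values fell between steps, so whole reads were not taken as recovered and no test for counts was run. The table lists 0 mitochondrial genes. Of its symbols, 23 had been turned into dates by spreadsheet software and were restored from their positions. GENCODE M21 (build GRCm38, the same assembly as mm10) holds 16850 of the symbols (98.5%), and biotypes were taken from it. Coordinates are those of the deposited table, given as 1-based start and end.

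Genes with at least 1 CPM in at least 2 of the 12 libraries were kept, which left 14001. Values were transformed to log2(CPM + 1), and every fold change is on that scale, which understates the change of genes with low values. A linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a trend, two-sided), with 6 residual degrees of freedom among libraries and 3.61 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over all genes tested within each comparison, with a threshold of 0.05, and every adjusted p of a gene comes from limma. The 9 comparisons were hydroxy against amino complex in all genotypes (the mean of the 3 differences) and in each genotype, KO against WT, HET against WT and KO against HET (each the mean over both complexes), and the difference in the effect of the complex between KO and WT and between HET and WT. Slc39a4, Mt1 and Mt2 were also compared between 4 KO and 4 WT or HET libraries by an exact two-sided permutation test, whose smallest possible p is 0.0286. The comparisons, model, threshold, gene lists and rule for named genes were fixed before the data were examined.

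The rule took Slc39a4, Mt1, Mt2 and Xist throughout. With 10 or more genes past the threshold, it took the 12 largest changes each way among genes at or above the median level, leaving out predicted genes and receptor segments. With fewer, it took all that passed and the smallest p-values up to 10 genes. It added up to 4 members with the smallest p of each list discussed and members that passed, and up to 5 genes each way that passed in both KO against WT and KO against HET. Some genes that meet the rule are not reported here. Gene lists covered zinc importers and exporters, zinc-responsive genes, amino acid and peptide transporters, iron and copper handling, the epithelial cell types, gut segments, other cell types of the gut wall, neighbouring organs, and stress, immune, metabolic and clock pathways. Of these, 41 lists had at least 3 tested members. The lists of eosinophil markers (2 tested members), stomach markers (2) and mitochondrially encoded genes (0) were not tested. Lists were tested with camera in limma at a preset correlation between genes of 0.01, with adjustment over the 41 lists of each comparison. They were tested again with an estimated correlation and with fry, whose mixed form asks whether members change in either direction. The mean level of each list per library was compared between genotypes by an exact permutation test.

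The model was tested on simulated libraries, with 100 genes changed 2-fold and 100 changed 4-fold in each of 5 draws. Of the genes changed 2-fold, 53.2% were recovered in KO against WT, 66.8% in hydroxy against amino over all genotypes and 22.4% in hydroxy against amino within KO. Of those changed 4-fold, 88.4%, 93.8% and 71.6% were recovered. False calls averaged 7.6, 9.2 and 5.4 genes, with a mean of 13683, 13679 and 13686 genes tested. The list test found the shifted list of 20 genes in 5 of 5 draws and called 1 of 200 unshifted lists, on independent genes.

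Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 CPM, quantile normalization or TMM factors, limma without a trend or with library weights, only the groups compared, an additive model, age as a covariate, a threshold of 0.10 and leaving out each library in turn. With 1 library of a group left, that library is assumed to vary like the other groups. Further alternatives were chosen after the data were seen. They left out the 2 HET libraries older than 300 days or the 2 libraries with more than 50 CPM of the ileal gene Fabp6, took a clock score or a smooth muscle score as a covariate, or left Slc39a4 out of the zinc importer and zinc-responsive lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No column or library was left out of the main model.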

Results

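RNA-seq was run on tissue labelled whole small intestine from 12 mice. Genotype (WT, HET or KO for the zinc importer gene Slc39a4, or Zip4) and zinc complex (amino or hydroxy) made 6 groups of 2. Libraries held 26.0 to 38.8 M reads, and 3 reads corresponded to 0.0773 to 0.115 CPM. A library is named by its group and replicate number, so that KO hydroxy 2 is replicate 2 of the KO mice fed the hydroxy complex. The design asks whether the end of the complex that carries zinc changes the gut, and whether that depends on this importer. Per the sample labels the KO diets held 40 ppm zinc and the other diets 15 ppm, so every difference between KO and another genotype is also a difference in zinc level.

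The targeted gene, Slc39a4 (chromosome 15, 76612383 to 76616852, minus strand, mm10), was lower in KO than in either other genotype. It stood at 72.1 ± 23.6 CPM in KO (SD, n = 4), 229 ± 33.1 in WT and 195 ± 74.4 in HET, so that KO kept 31.4% of the WT level and 37.0% of the HET level. Every KO library (42.0 to 91.6 CPM) lay below every WT and HET library (117 to 267 CPM), with an exact two-sided permutation p of 0.0286 against each, the smallest the design allows. In the model over all genes the log2 change was −1.71 (SE 0.28, adjusted p = 0.0736) against WT and −1.40 (SE 0.28, adjusted p = 0.0273) against HET. The call against HET ended without HET amino 2 (−1.13, adjusted p = 0.0584), HET hydroxy 1 (−1.62, 0.0677), KO amino 1 (−1.40, 0.0823), KO amino 2 (−1.41, 0.103), KO hydroxy 1 (−1.25, 0.0742), KO hydroxy 2 (−1.56, 0.0506), WT amino 1 (−1.40, 0.0504) or WT amino 2 (−1.40, 0.0506). HET libraries held 117 and 145 CPM in the mice aged 363 and 338 days and 249 and 267 CPM in those aged 141 and 143 days, and the difference between HET and WT did not pass (−0.31, adjusted p = 0.649). The deleted part of the gene is not given in the sources used here, so reads that remain in KO cannot be assigned to a deleted or kept part. Metallothioneins, small metal-binding proteins whose genes respond to zinc, showed no difference that passed. Mt1 (chromosome 8, 94179089 to 94180327) stood at 28.5 ± 32.3 CPM in KO, 37.2 ± 11.6 in WT (exact p = 0.629) and 40.8 ± 19.7 in HET (exact p = 0.514). Mt2 (chromosome 8, 94172618 to 94173567) stood at 4.59 ± 5.71 CPM in KO, 3.81 ± 2.46 in WT (exact p = 0.914) and 5.12 ± 3.75 in HET. The KO spread came from KO hydroxy 2, with 76.8 CPM of Mt1 and 13.1 CPM of Mt2.

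**Figure D1:**
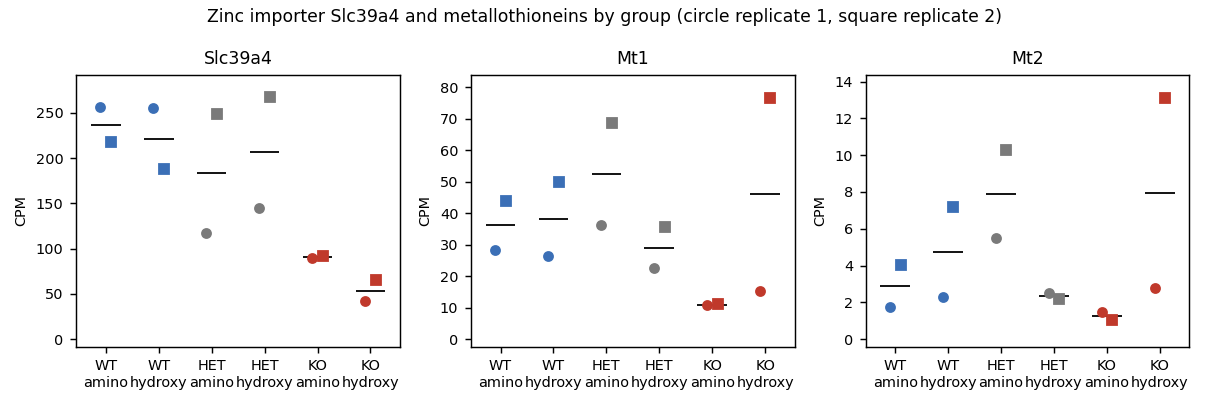
CPM of Slc39a4, Mt1 and Mt2 (vertical axes) in the 6 groups (horizontal axis), with 1 point per library, circles for replicate 1, squares for replicate 2 and a line at the group mean. The 4 KO libraries hold 42.0 to 91.6 CPM of Slc39a4, below all others, and KO hydroxy 2 has 76.8 CPM of Mt1.

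Sex-linked genes went against the sex labels of both KO amino libraries. KO amino 1, labelled male, held 244 CPM of Xist, the RNA that silences an X chromosome in females, and its 4 Y-linked genes were at the floor. KO amino 2, labelled female, held 0.155 CPM of Xist and 32.2 CPM of the Y-linked helicase gene Ddx3y. The other 10 libraries are labelled male and held at most 0.877 CPM of Xist and 24.99 to 44.3 CPM of Ddx3y. The libraries labelled KO amino 1 and 2 belong to 1 group, so an exchange between them would leave each group of the design as it is.

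Several cell and tissue programmes varied between libraries of the same genotype. Myh11, the smooth muscle myosin, ranged from 209 to 2215 CPM, with 2215 and 1918 in the 2 older HET mice and 410 and 337 in the younger. Egr1, an immediate early transcription factor, stood at 874 and 657 CPM in the older HET mice, 50.8 and 12.1 in the younger, 7.94 to 27.1 in WT and 10.6 to 22.7 in KO. The clock output gene Dbp ranged from 7.20 to 164 CPM. Fabp6, the ileal bile acid binding protein, stood at 259 CPM in WT hydroxy 1, 99.3 in HET amino 2 and below 1 in the other 10. The gut segment may thus differ by library. HET amino 2 also had 1539 genes at the floor, against 478 to 860 in the others. The first principal component held 38.2% of the variance and the second 24.6%. Across genes, which are not independent replicates, libraries of 1 group correlated with a median r of 0.964 over 6 pairs (0.930 to 0.976) and libraries of different groups with a median of 0.956 over 60 pairs (0.897 to 0.985).

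**Figure D2:**
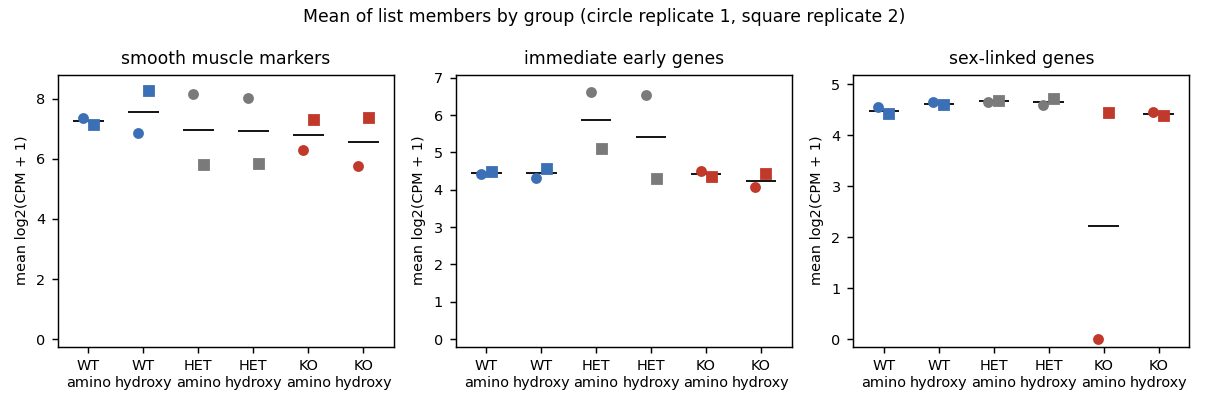
Mean log2(CPM + 1) of the smooth muscle markers, immediate early genes and sex-linked genes (vertical axes) in the 6 groups (horizontal axis), with 1 point per library, circles for replicate 1, squares for replicate 2 and a line at the group mean. Replicate 1 of each HET group (363 and 338 days) is the higher in smooth muscle and immediate early genes. WT hydroxy 2 (221 days) is highest in smooth muscle, and KO amino 1 is at the floor of sex-linked genes.

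Hydroxy against amino complex over all genotypes takes the mean of the differences in WT, HET and KO, which need not be alike. No single gene passed, and 4 gene lists stood higher with the hydroxy complex and 5 lower, none of them called with an estimated correlation. Ribosomal protein genes rose as a list (median log2 change 0.36, 23 of 26 above 0, adjusted p = 2.53e-04), as did proliferation genes (0.36, 20 of 20 above 0, adjusted p = 2.93e-04), with an adjusted p of 0.983 for each with an estimated correlation. ATF4 targets, the amino acid response (0.39, adjusted p = 0.0117), and PPARA targets of fatty acid oxidation (0.25, adjusted p = 0.0152) rose as lists too, again with an adjusted p of 0.983 with an estimated correlation. Absorptive enterocyte markers fell as a list (−0.30, adjusted p = 5.28e-04), and so did immediate early genes (−0.17, adjusted p = 0.0155) and T cell and intraepithelial lymphocyte markers (−0.14, adjusted p = 0.034), each with an adjusted p of 0.983 with an estimated correlation. Circadian clock genes fell as a list (−0.23, adjusted p = 0.00164, and adjusted p = 0.946 with an estimated correlation). Amino acid and peptide transporters also fell as a list (−0.17, adjusted p = 0.00274, and adjusted p = 0.316 with an estimated correlation). Limma called 0 of 14001 genes, with 1255 at an unadjusted p under 0.05, and adjusted over the list alone only Slc25a20, the mitochondrial carnitine carrier, passed (0.48). The genes with the smallest p were Gatsl2 (−0.80, SE 0.14), the citrate and succinate transporter gene Slc13a2 (−0.78), the clock-linked deadenylase gene Noct (−0.99) and H2-Q10 (0.66), all with an adjusted p of 0.544. Slc39a4 (−0.23), Mt1 (0.28) and Mt2 (0.27) did not pass. Fry's test of whether the members of a list move one way called 0 lists in this and in each of the other comparisons.

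The shared differences rested in part on single libraries. The enterocyte call ended without HET hydroxy 1 (−0.20, adjusted p = 0.103) or KO hydroxy 2 (−0.18, 0.0586), and the median was −0.46 without HET amino 1 and −0.13 without HET amino 2. The fatty acid oxidation call ended without KO amino 1 (0.17, adjusted p = 0.133), KO hydroxy 1 (0.30, 0.16) or WT amino 2 (0.24, 0.0501), and its median was 0.15 without HET amino 2. The immediate early call ended without HET amino 1 (0.04, adjusted p = 0.312) or HET hydroxy 2 (0.23, 0.515). Its median was −0.46 without HET amino 2 or HET hydroxy 1, −0.08 without KO hydroxy 1, −0.26 without KO hydroxy 2 and −0.28 without WT hydroxy 2. The T cell call ended without HET amino 2 (0.02, adjusted p = 0.756), HET hydroxy 1 (−0.16, 0.148), KO amino 1 (−0.06, 0.168), KO hydroxy 2 (−0.12, 0.268) or WT amino 2 (−0.07, 0.492), and reversed without WT hydroxy 2 (0.07, 0.899). Its median was −0.34 without HET amino 1, −0.25 without KO amino 2, −0.29 without WT amino 1 and −0.39 without WT hydroxy 1. Without KO hydroxy 2 the medians of proliferation (0.20), ribosomal (0.22) and ATF4 (0.25) genes were smaller and still passed. The transporter median was −0.11 without HET amino 2 or KO amino 2 and −0.10 without WT amino 1, and the clock median was −0.13 without WT amino 1 and −0.36 without WT amino 2. Of the other settings, those with the older HET mice or the Fabp6 libraries left out and those with a clock or smooth muscle score were chosen after the data were seen. The proliferation call ended without the older HET mice (0.27, adjusted p = 0.0526), the enterocyte (−0.20, 0.0954) and immediate early (−0.23, 0.0954) calls with quantile normalization, and the clock call with the clock score (−0.07, 0.0717). The T cell call ended with no filter (adjusted p = 0.0643), a mean of at least 5 CPM (0.0652), quantile normalization (0.241), TMM factors (0.113) or age as a covariate (0.0676). Its median was −0.36 without the older HET mice and −0.47 with the clock score. The immediate early median was −0.27 without the older HET mice or with age, −0.41 without the Fabp6 libraries and −0.05 with the clock score. The transporter median was −0.11 without the Fabp6 libraries, and the fatty acid oxidation median 0.38 with the clock score. Single genes passed only without KO amino 1 (1 gene) or KO amino 2 (2 genes).

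In WT mice the complex left no gene past the threshold, and the lists that moved were small shifts. Tuft cell markers rose as a list (0.45, 9 of 9 above 0, adjusted p = 0.0177, and adjusted p = 0.963 with an estimated correlation). B cell and plasma cell markers fell as a list (−0.28, 0 of 11 above 0, adjusted p = 1.44e-04), as did enterocyte markers (−0.17, adjusted p = 9.34e-05) and genes of the unfolded protein response (−0.14, adjusted p = 0.00215). These lists too had an adjusted p of 0.963 with an estimated correlation. Amino acid and peptide transporters fell as a list (−0.09, adjusted p = 0.0219, and adjusted p = 0.681 with an estimated correlation). Limma called 0 genes, with 144 at an unadjusted p under 0.05, and 0 list members adjusted over the list alone. Slc13a2 (−1.30), Noct (−1.63), Rin2 (1.07), the growth inhibitor gene Btg1 (1.01), Crebrf (1.44) and Klhl24 (1.32) had the smallest p, each with an adjusted p of 1. Slc13a2 stood at 136 ± 4.89 CPM with hydroxy and 339 ± 61.1 with amino (SD, n = 2), and Noct at 22.1 ± 0.751 and 70.9 ± 11.8 CPM. The median log2 change of all genes was 0.10 in WT and −0.00 after quantile normalization, so shifts of this size in WT are relative to it. The calls ended without WT amino 1 for enterocyte markers (0.01, adjusted p = 0.39) and transporters (−0.17, 0.39). They ended without WT amino 2 for B cell markers (−0.03, adjusted p = 0.422), the unfolded protein response (0.17, 0.953) and tuft cell markers (0.56, 0.101). Without WT hydroxy 2 all 5 ended, at −0.15 for enterocyte markers (adjusted p = 0.0704), −0.15 for B cell markers (0.351), 0.10 for the unfolded protein response (0.912), 0.05 for tuft cell markers (0.884) and −0.08 for transporters (0.157). Without WT hydroxy 1 the medians grew to 0.95 for tuft cell markers, −0.41 for enterocyte markers, −0.34 for the unfolded protein response and −0.54 for B cell markers. Without WT amino 1 they were −0.32 for the unfolded protein response and −0.62 for B cell markers, and without WT amino 2 −0.44 for enterocyte markers and −0.13 for transporters. In other settings the calls of enterocyte markers (−0.03, adjusted p = 0.471) and transporters (−0.09, 0.212) ended with quantile normalization, that of transporters with TMM factors (−0.16, 0.125), that of tuft cell markers at a mean of at least 5 CPM (0.43, 0.28) and that of the unfolded protein response with the smooth muscle score (−0.06, 0.0521). With the clock score tuft cell markers were at 0.86, B cell markers at −0.47, enterocyte markers at −0.27 and the unfolded protein response at −0.36.

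In HET mice Paneth and enteroendocrine cell markers stood higher with the hydroxy complex. Paneth cell markers rose as a list (1.17, 17 of 18 above 0, adjusted p = 7.2e-04), and so did enteroendocrine cell markers (0.51, 13 of 16 above 0, adjusted p = 0.0375), while circadian clock genes fell as a list (−0.34, adjusted p = 0.0375). Each had an adjusted p of 0.954 with an estimated correlation. Limma called 0 genes, with 375 at an unadjusted p under 0.05, and 0 list members adjusted over the list alone. Cystm1 (1.87), Ebpl (0.81), Snapc5 (0.98) and Edf1 (0.90) had the smallest p, each with an adjusted p of 1. The Paneth call reversed in its test without HET amino 1 (0.13, adjusted p = 0.95), ended without HET hydroxy 2 (0.68, 0.286) and stood at 1.92 without HET amino 2. The enteroendocrine call ended without HET amino 2 (−0.09, adjusted p = 0.541) or HET hydroxy 2 (0.60, 0.125) and stood at 0.95 without HET amino 1. The clock call ended without HET amino 1 (−0.12, adjusted p = 0.195) or HET hydroxy 1 (−0.39, 0.459) and stood at −0.84 without HET amino 2. In other settings the enteroendocrine call ended with a pseudocount of 5 (0.32, adjusted p = 0.0509) or without the Fabp6 libraries (−0.09, 0.345), and the clock call with no filter (0.0699) or library weights (0.0527). With the clock score Paneth cell markers were at 0.71 and clock genes at −0.20. Without HET amino 1, 6 genes passed. HET amino 2 held 99.3 CPM of Fabp6 and 1539 genes at the floor. Replicates 1 are the older mice, so age may add to spread.

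In KO mice the hydroxy complex went with higher lists of proliferation, B cell, amino acid response and ribosomal protein genes and a lower list of enterocyte genes, none of them called with an estimated correlation. Proliferation genes rose as a list (0.94, 20 of 20 above 0, adjusted p = 6.06e-09, and adjusted p = 0.81 with an estimated correlation), and 12 of them passed when adjusted over the list alone, among them the replication genes Pcna (0.91) and Mcm2 (1.10) and the mitotic genes Bub1 (1.21) and Ccna2 (1.14). B cell and plasma cell markers rose as a list (1.53, 11 of 11 above 0, adjusted p = 2.31e-04, and adjusted p = 0.81 with an estimated correlation), with 7 members past the threshold adjusted over the list alone, such as the B cell receptor genes Cd79a (1.64) and Cd79b (1.60), and Fcer2a (1.89). ATF4 targets rose as a list (0.97, adjusted p = 5.32e-04, and adjusted p = 0.81 with an estimated correlation), with 7 members adjusted over the list alone, such as the serine synthesis gene Psat1 (1.90), Mthfd2 (1.32), Asns (1.30) and Chac1 (1.87). Enterocyte markers fell as a list (−0.57, adjusted p = 4.24e-04, and adjusted p = 0.81 with an estimated correlation), with the lactase gene Lct at −1.57 and 0 members past the threshold. Fatty acid oxidation genes rose (0.44, adjusted p = 0.0148) and clock genes fell (−0.36, adjusted p = 0.0111) as lists, both with an adjusted p of 0.81 with an estimated correlation. Ribosomal protein genes rose as a list (0.79, adjusted p = 2.72e-06, and adjusted p = 0.865 with an estimated correlation). Fibroblast markers fell as a list (−0.55, adjusted p = 0.00247, and adjusted p = 0.916 with an estimated correlation). Amino acid and peptide transporters fell as a list (−0.35, adjusted p = 0.0148, and adjusted p = 0.739 with an estimated correlation), with Slc6a6 (−0.77) and Slc36a1 (−1.50) past the threshold adjusted over the list alone. The 4 Y-linked genes were higher as a list (2.11, adjusted p = 0.0429, and adjusted p = 0.916 with an estimated correlation), and KO amino 1 is the library without Y-linked reads.

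Over all genes limma called 0 in this comparison within KO, with 1921 at an unadjusted p under 0.05. Gatsl2 stood at 6.99 ± 1.56 CPM with hydroxy and 30.3 ± 2.21 with amino (SD, n = 2, log2 change −1.98, SE 0.25, adjusted p = 0.159). Slc39a4 stood at −0.79 (SE 0.39, adjusted p = 0.41), Mt1 at 1.58 (adjusted p = 0.335) and Mt2 at 1.70 (adjusted p = 0.317). Without KO amino 1, 1 gene passed, and without KO amino 2, 4 genes passed. Without KO hydroxy 2 the calls of enterocyte markers (−0.10, adjusted p = 0.33) and transporters (−0.30, 0.225) ended. In that setting proliferation was at 0.52, ATF4 targets at 0.55, ribosomal proteins at 0.37 and fibroblast markers at −0.9998. Without KO hydroxy 1 the calls of fibroblast markers (−0.09, adjusted p = 0.256), fatty acid oxidation (0.68, 0.256) and sex-linked genes (2.08, 0.27) ended, and enterocyte markers were at −1.04, clock genes at −0.20 and ribosomal proteins at 1.19. Without KO amino 1 the calls of fatty acid oxidation (0.25, adjusted p = 0.33) and transporters (−0.28, 0.0563) ended, sex-linked genes reversed (−0.01, 0.753) and clock genes were at −0.61. Without KO amino 2 the clock call ended (−0.20, adjusted p = 0.135) and sex-linked genes were at 4.24. The sex-linked call also ended without HET amino 1 (adjusted p = 0.0813), HET amino 2 (0.082), HET hydroxy 1 (0.051), HET hydroxy 2 (0.0513), WT amino 1 (0.0506) or WT amino 2 (0.0509). In other settings it ended with no filter (1.83, adjusted p = 0.244), a mean of at least 5 CPM (1.83, 0.346), a pseudocount of 5 (1.10, 0.0589), library weights (0.145) or the smooth muscle score (0.0991), and without the Fabp6 libraries (0.085). At a mean of at least 5 CPM the calls of B cell markers (0.32, adjusted p = 0.13) and fatty acid oxidation (0.44, 0.053) ended, and with TMM factors that of transporters (−0.50, 0.0794). With a pseudocount of 5 the B cell median was 0.56.

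**Figure D3:**
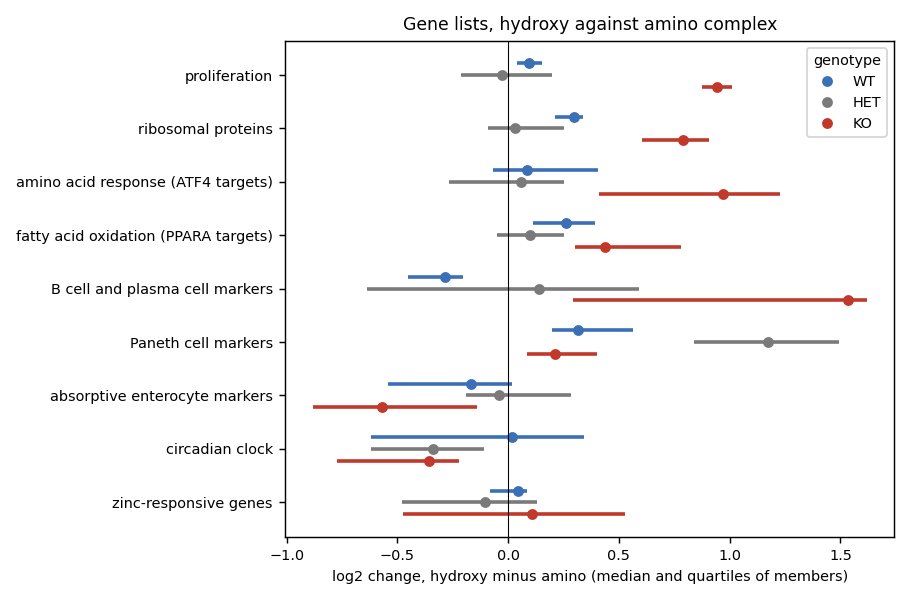
Log2 change, hydroxy minus amino (horizontal axis), of the members of 9 gene lists (vertical axis), with a point at the median and a bar over the quartiles for WT, HET and KO. Proliferation genes have medians of 0.94 in KO and 0.10 in WT, and Paneth cell markers have a median of 1.17 in HET.

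The difference in the effect of the complex between genotypes was tested directly. Proliferation genes responded more in KO than in WT (difference of log2 changes 0.79, 20 of 20 above 0, adjusted p = 5.77e-09), as did B cell and plasma cell markers (1.75, 11 of 11 above 0, adjusted p = 2.08e-08, with 6 members past the threshold adjusted over the list alone). Each had an adjusted p of 0.866 with an estimated correlation. The proliferation difference was 1.26 without KO hydroxy 1, 0.35 without KO hydroxy 2 and 0.49 without WT amino 2, and passed each time. Altogether 7 lists differed between KO and WT (5 higher, 2 lower) and 3 between HET and WT (2 higher, 1 lower), and 0 did with an estimated correlation. Limma called 0 genes for either difference, with 530 at an unadjusted p under 0.05 for KO and 222 for HET, and 2 genes passed for KO without KO amino 2. Among the smallest p were those of Lrp12 (−2.05), Timmdc1 (1.31), Gatsl2 (−1.69) and Crebrf (−2.18) for KO, each with an adjusted p of 0.992. For HET they were those of Crebrf (−1.83), Klhl24 (−1.67), Rin2 (−1.17) and Snapc5 (1.18), each with an adjusted p of 1. Slc39a4 (−0.68), Mt1 (1.54) and Mt2 (1.22) did not pass in KO against WT.

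KO against WT asks what differs in mice labelled as lacking the importer. The MHC class I gene H2-Q10 and the antiviral genes Oas2 and Oas1b were higher in KO, and Krba1 was lower. H2-Q10, a secreted MHC class I protein (chromosome 17, 35470089 to 35474563), rose from 4.64 ± 1.54 CPM in WT to 42.9 ± 21.04 in KO (SD, n = 4, log2 change 2.87, SE 0.17, adjusted p = 2e-04), with 4.59 ± 0.406 in HET. Oas2, which makes 2'-5' oligoadenylate on sensing double-stranded RNA (chromosome 5, 120730333 to 120749848), rose from 1.90 ± 1.05 to 30.0 ± 20.8 CPM (3.21, SE 0.39, adjusted p = 0.0487). Its relative Oas1b (chromosome 5, 120812635 to 120824160, a polymorphic pseudogene in the annotation) rose from 1.55 ± 0.273 to 7.90 ± 2.55 CPM (1.77, SE 0.21, adjusted p = 0.0487). Krba1 (chromosome 6, 48395586 to 48419855) fell from 17.1 ± 5.30 to 4.19 ± 2.20 CPM (−1.87, SE 0.23, adjusted p = 0.0487), with 14.6 ± 1.79 in HET. These 4 were the genes limma called, with 1370 at an unadjusted p under 0.05. H2-Q10 and the Oas1 family have close paralogs, so their reads are uncertain. H2-Q10 passed in 28 of 28 settings (adjusted p up to 0.00606). The calls of Oas1b, Oas2 and Krba1 ended without HET amino 1 (adjusted p = 0.0662), HET amino 2 (0.0687), HET hydroxy 1 (0.0712) or HET hydroxy 2 (0.0717), which leave the log2 changes as they are. All 3 also ended without KO amino 1 (1.74, 2.86 and −1.92, adjusted p from 0.14), KO hydroxy 1 (1.64, 3.02 and −1.74, 0.218), WT amino 1 (1.73, 2.87 and −1.65, from 0.271), WT hydroxy 1 (1.69, 3.30 and −1.79, from 0.172) or WT hydroxy 2 (1.85, 3.13 and −1.95, 0.189). Oas1b ended without KO amino 2 (1.81, adjusted p = 0.0703) or WT amino 2 (1.81, 0.0732), Oas2 without KO hydroxy 2 (3.41, 0.0776), and Krba1 without KO amino 2 (−1.82, 0.0917) or KO hydroxy 2 (−2.00, 0.061). All 3 calls ended as well with no filter (adjusted p = 0.0506), with a pseudocount of 0.1 (0.0651), with TMM factors (0.0511), with only the groups compared (0.0735 to 0.0882), without the older HET mice (0.0723 to 0.0862) and without the Fabp6 libraries (0.178 to 0.197). With a mean of at least 5 CPM those of Oas2 and Krba1 ended (0.0542) and Oas1b was not tested. The number of genes called was 14 without KO amino 2, 6 without KO hydroxy 2, 3 without KO hydroxy 1 and 4 without WT amino 2. It was 1 without each of the other 8 libraries.

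Interferon response genes rose as a list in KO against WT (median 1.67, quartiles 0.77 to 2.30, 18 of 22 above 0, adjusted p = 9.88e-13, and adjusted p = 0.651 with an estimated correlation). Of these genes 1 passed over all genes and 13 adjusted over the list alone, and fry's mixed test, which asks for change in either direction, passed (adjusted p = 0.0155), while its test of 1 direction did not (adjusted p = 0.194). Ifi44 (3.88, adjusted p = 0.053), Ifit3 (2.54, 0.053), the virion-tethering gene Bst2 (2.46, 0.055) and the ubiquitin-like modifier gene Isg15 (2.85, 0.064) lay just over the threshold. Isg15 stood at 181 ± 150 CPM in KO and 20.6 ± 9.12 in WT, and Bst2 at 146 ± 107 and 19.2 ± 5.36 (SD, n = 4). The mean level of the list was 4.40 to 6.09 on the log2(CPM + 1) scale in KO libraries, 2.95 to 4.26 in WT and 3.48 to 4.38 in HET, with an exact p of 0.0286 for KO against WT and an adjusted exact p of 0.502 over the 41 lists. At the preset correlation the list passed in 26 of 26 settings, with a median of 1.19 to 2.20, and with an estimated correlation it did not pass. Pmm1, a phosphomannomutase gene on chromosome 15 (81951106 to 81960930), stood at 72.1 ± 23.3 CPM in KO and 10.4 ± 2.54 in WT (2.64, adjusted p = 0.055). The remaining genes with the smallest p, Lrp12 (−1.27, adjusted p = 0.0562) and Ndor1 (−1.37, adjusted p = 0.0565), did not pass.

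**Figure D4:**
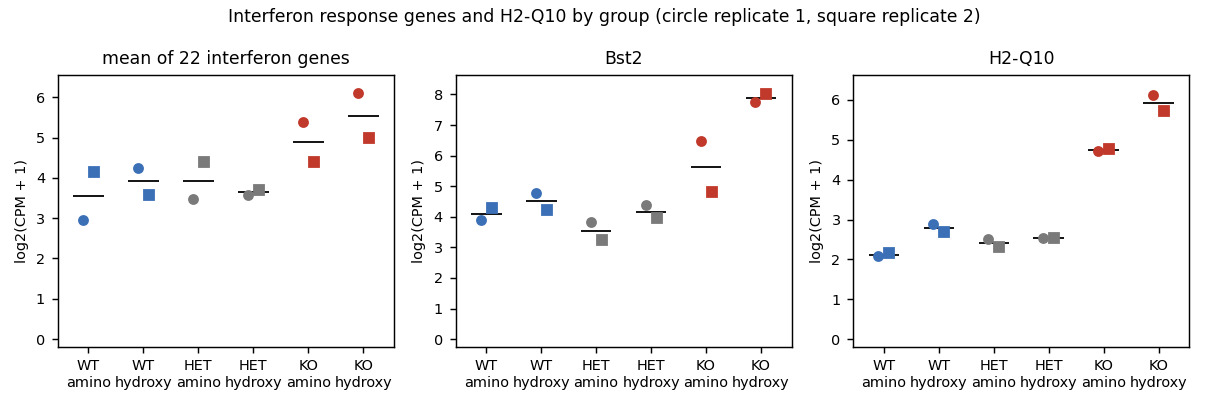
Log2(CPM + 1) of the mean of 22 interferon response genes, of Bst2 and of H2-Q10 (vertical axes) in the 6 groups (horizontal axis), with 1 point per library, circles for replicate 1, squares for replicate 2 and a line at the group mean. The mean of the 22 genes is 4.40 to 6.09 in the KO libraries, above the 2.95 to 4.26 of WT and the 3.48 to 4.38 of HET.

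Lists of proliferation, fatty acid oxidation, ATF4 target and ribosomal protein genes also stood higher in KO than in WT, none of them called with an estimated correlation. Proliferation genes rose as a list (0.60, 20 of 20 above 0, adjusted p = 1.06e-09, and adjusted p = 0.657 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. PPARA targets of fatty acid oxidation rose as a list (0.40, adjusted p = 2.99e-04, and adjusted p = 0.651 with an estimated correlation). Adjusted over the list alone, 6 were higher and 1 lower, with the acyl-CoA dehydrogenase gene Acadl at 1.57, Slc25a20 at 0.51, Hadha at 0.48 and the lipid droplet gene Plin2 at 0.62. ATF4 targets rose as a list (0.41, adjusted p = 7.97e-04, and adjusted p = 0.652 with an estimated correlation), with 7 higher adjusted over the list alone, such as Chac1 (1.49), Mthfd2 (0.91), Asns (0.86) and Slc7a1 (0.79). Ribosomal protein genes rose as a list (0.31, 26 of 26 above 0, adjusted p = 0.00126, and adjusted p = 0.948 with an estimated correlation). Zinc-responsive genes, a list that holds the knocked-out gene Slc39a4, were lower with it (−0.20, adjusted p = 0.0266, adjusted p = 0.651 with an estimated correlation, and adjusted p = 0.0196 in fry's mixed test). Without Slc39a4 the 10 other members did not pass (−0.20, adjusted p = 0.165, and adjusted p = 0.306 in the mixed test). Adjusted over the list alone, Slc39a4 (adjusted p = 0.00133) and the zinc exporter gene Slc30a2 (−0.99, adjusted p = 0.0359) passed, and without Slc39a4 in the list 0 members did, while Mt1 (−0.84, adjusted p = 0.566 over all genes) and Mt2 (−0.12, 0.927) did not. Zinc importers as a list did not pass (0.10, adjusted p = 0.907), with Slc39a4 the 1 member past the threshold adjusted over the list alone. Its mixed test passed with Slc39a4 (adjusted p = 0.00858) and did not without it (adjusted p = 0.592). Amino acid and peptide transporters fell as a list (−0.16, adjusted p = 0.036, and adjusted p = 0.651 with an estimated correlation).

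Markers of the gut wall and of the distal gut fell as lists in KO against WT, as did the sex-linked genes. Fibroblast markers were at −0.56 (0 of 13 above 0, adjusted p = 5.65e-05, and adjusted p = 0.875 with an estimated correlation), with the collagen gene Col3a1 at −0.62. Distal intestine markers, which include Fabp6, were at −0.73 (adjusted p = 0.00134, and adjusted p = 0.883 with an estimated correlation). Enteric neuron and glia markers (−0.55, adjusted p = 0.00193), smooth muscle markers (−0.77, adjusted p = 0.00276) and endothelial markers (−0.22, adjusted p = 0.036) each had an adjusted p of 0.948 with an estimated correlation. Sex-linked genes were at −1.20 (adjusted p = 0.0266, and adjusted p = 0.875 with an estimated correlation), and KO amino 1 is the library without Y-linked reads. In all these lists 0 members passed adjusted over the list alone.

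Of the 13 lists called in KO against WT, 6 passed without each library in turn, and they are the interferon, proliferation, fibroblast, fatty acid oxidation, ATF4 and neuron and glia lists. Without KO hydroxy 2 the calls of ribosomal proteins (0.13, adjusted p = 0.159), distal intestine (−0.73, 0.0973), sex-linked genes (−1.18, 0.121) and transporters (−0.15, 0.294) ended. Proliferation was then at 0.38, smooth muscle at −1.17, neuron and glia at −0.88, endothelium at −0.49 and zinc-responsive genes at −0.34. Without KO hydroxy 1 the calls of smooth muscle (−0.33, adjusted p = 0.068) and endothelium (−0.02, 0.231) ended, with fibroblasts at −0.31, neuron and glia at −0.25, ribosomal proteins at 0.51 and transporters at −0.28. Without KO amino 1 the sex-linked call ended (−0.10, adjusted p = 0.502) and smooth muscle was at −0.50. Without KO amino 2 the calls of transporters (−0.13, adjusted p = 0.075) and endothelium (−0.25, 0.0683) ended, with fatty acid oxidation at 0.21 and sex-linked genes at −2.45. Without WT hydroxy 1 the calls of distal intestine (−0.24, adjusted p = 0.211), sex-linked genes (−1.20, 0.0817), zinc-responsive genes (−0.32, 0.0556) and transporters (−0.20, 0.0821) ended, with endothelium at −0.38 and neuron and glia at −0.83. Without WT hydroxy 2 the calls of smooth muscle (−0.39, adjusted p = 0.0514) and endothelium (−0.12, 0.0845) ended, with distal intestine at −1.27 and neuron and glia at −0.32. Without WT amino 1 the calls of transporters (−0.12, adjusted p = 0.0559) and endothelium (−0.19, 0.0605) ended, with zinc-responsive genes at −0.36 and ribosomal proteins at 0.19. Zinc-responsive genes were at −0.36 without WT amino 2. The transporter call also ended without HET hydroxy 1 (adjusted p = 0.0531) or HET hydroxy 2 (0.0536). In other settings the sex-linked call ended with no filter (−1.09, adjusted p = 0.141), a mean of at least 5 CPM (−1.09, 0.0862), TMM factors (0.0577), library weights (0.094) or age (0.0504), and without the older HET mice (0.0662) or the Fabp6 libraries (0.128). The transporter call ended with no filter (adjusted p = 0.0504), TMM factors (0.151) or no trend (0.0518) and without the Fabp6 libraries (0.052), and the zinc-responsive call with TMM factors (0.0577). The endothelial call ended with no filter (adjusted p = 0.0504) or the clock score (−0.14, 0.097), and the distal intestine call without the Fabp6 libraries (−0.24, 0.138). With the smooth muscle score, the mean of that list, smooth muscle itself had to end (−0.00). The calls of endothelium (0.05, adjusted p = 0.726) and neuron and glia (−0.05, 0.115) ended. Fibroblasts were at −0.26, ATF4 targets at 0.74 and distal intestine at −1.33. With the clock score smooth muscle was at −0.47, neuron and glia at −0.36 and zinc-responsive genes at −0.31.

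The other 28 lists were not called in KO against WT, and their medians lay between −0.47 and 0.35. Medians were 0.11 for zinc exporters, 0.16 for iron handling and 0.00 for copper handling. Among epithelial cells they were −0.27 for enterocytes, 0.15 for stem cells, −0.08 for Paneth cells, −0.14 for goblet cells, −0.09 for enteroendocrine cells and 0.08 for tuft cells. Among gut segments and organs they were 0.19 for proximal intestine, 0.19 for colon, 0.35 for liver and 0.11 for pancreatic acinar cells. Among other cells they were 0.09 for T cells, 0.30 for B and plasma cells, −0.08 for myeloid cells, −0.47 for mast cells, −0.20 for adipocytes and −0.17 for red blood cells. Among pathways they were −0.46 for MHC class II, −0.16 for antimicrobial defence, 0.19 for the unfolded protein response, 0.13 for heat shock, 0.21 for cholesterol synthesis, 0.20 for xenobiotic metabolism, −0.10 for the clock and −0.04 for immediate early genes. The adjusted p lay between 0.0935 for the unfolded protein response and 0.947 for red blood cells and tuft cells. Median, mean and test differed in sign for colon markers (0.19, −0.08, higher), zinc importers (0.10, −0.08, lower), tuft cells (0.08, 0.04, lower) and red blood cells (−0.17, −0.05, higher), and for no called list of any comparison.

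KO against HET compares the knockout with carriers of 1 intact copy. Interferon genes were again higher in KO as a list, and fibroblast, immediate early, myeloid and endothelial markers were lower as lists, each with an adjusted p of 0.958 with an estimated correlation. Isg15 rose from 8.99 ± 3.87 CPM in HET to 181 ± 150 in KO (SD, n = 4, log2 change 3.91, SE 0.44, adjusted p = 0.0124). Ifi44 (3.89, adjusted p = 0.0131), Oas1g (3.35, 0.0144), Oas1a (3.17, 0.0137), the negative regulator gene Usp18 (3.09, 0.0222), Bst2 (2.90, 0.0124), Ifit3 (2.73, 0.0124), Rtp4 (2.56, 0.0124) and the RNA sensor gene Dhx58 (2.32, 0.0177) rose as well. So did H2-Q10 (2.85, adjusted p = 2.18e-04), Pmm1 (2.79, 0.0136) and the apolipoprotein gene Apoc2 (2.39, 0.0476). Among genes at or above the median level, the largest falls were in the nuclear RNA Malat1 (−2.53, adjusted p = 0.0233), the protease gene Adamts1 (−2.52, 0.0466), Tmem117 (−2.48, 0.0492), the cobalamin receptor gene Cubn (−2.34, 0.0367) and the laminin genes Lama3 (−2.29, 0.0317) and Lama5 (−1.94, 0.022). Hhip (−2.03, adjusted p = 0.0167), Hspa12a (−1.90, 0.0331), the plasminogen activator gene Plau (−1.79, 0.0475), the collagen genes Col23a1 (−1.79, 0.0331) and Col12a1 (−1.68, 0.0234) and the matrix gene Npnt (−1.65, 0.0144) fell too. The zinc exporter gene Slc30a6 (0.62, adjusted p = 0.044) and the copper chaperone gene Cox17 (1.59, 0.02) rose, while Mt1 (−0.90, 0.225) and Mt2 (−0.40, 0.588) did not pass. Limma called 957 genes, 481 higher and 476 lower.

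The count in KO against HET depended on single libraries. It was 1393 without HET amino 1, 108 without HET amino 2, 1 without HET hydroxy 1, 29 without KO amino 1, 27 without KO amino 2, 109 without KO hydroxy 1 and 170 without KO hydroxy 2. It was 289 without WT amino 1, 292 without WT amino 2, 420 without WT hydroxy 1 and 479 without WT hydroxy 2, which only help to estimate the spread, and 10 without any WT library. Without both older HET mice, the libraries with 2215 and 1918 CPM of Myh11, it was 448, of which 295 were among the 957, and 2 without both Fabp6 libraries. Of the 24 genes named for the largest changes, 22 still passed without HET amino 1, 15 without HET amino 2, 1 without HET hydroxy 1 and 20 without HET hydroxy 2. The number was 7 without KO amino 1, 8 without KO amino 2, 10 without KO hydroxy 1 and 15 without KO hydroxy 2. It was 18 without WT amino 1 or WT amino 2, 19 without WT hydroxy 1 and 20 without WT hydroxy 2.

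By gene list, KO against HET gave 9 calls, each with an adjusted p of 0.958 with an estimated correlation. Interferon genes rose as a list (1.77, adjusted p = 1.03e-05), with 10 higher and 1 lower, the GTPase gene Gbp4, over all genes and 12 higher and 2 lower adjusted over the list alone. Fatty acid oxidation genes rose as a list (0.56, adjusted p = 8.95e-05), with Slc25a20, Acadl and Plin2 past the threshold over all genes and 8 higher adjusted over the list alone. Fibroblast markers fell as a list (−1.05, adjusted p = 5.08e-04), with 6 lower over all genes, such as the growth factor receptor gene Pdgfrb (−1.49) and the collagen genes Col3a1 (−1.31) and Col6a2 (−1.31), and 8 adjusted over the list alone. Immediate early genes fell as a list (−1.09, adjusted p = 0.00187), with Fosb (−2.62) lower over all genes and 6 adjusted over the list alone. Myeloid markers fell as a list (−0.47, adjusted p = 0.00379), with the macrophage genes Csf1r (−1.14), Adgre1 (−1.05) and Cx3cr1 (−0.94) and the integrin gene Itgax (−1.31) lower over all genes and 6 adjusted over the list alone. Endothelial markers fell as a list (−0.60, adjusted p = 0.00397), with the receptor genes Kdr (−1.22), Flt1 (−1.45) and Eng (−1.06) lower over all genes and 4 adjusted over the list alone. Ribosomal protein genes (0.30, adjusted p = 0.0264), proliferation genes (0.26, 0.0345) and ATF4 targets (0.51, 0.0368) rose as lists. In them Rpl3 (−1.82) was lower and Pcna (0.73) and Chac1 (1.84) were higher over all genes, and the same numbers passed adjusted over the list alone. Fry's mixed test passed for 10 lists, and its test of 1 direction for 0.

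These list calls moved with the older HET mice and with single libraries. The mean level of the fibroblast markers on the log2(CPM + 1) scale was 6.53 and 6.59 in the older HET mice, 5.43 and 5.51 in the younger and 4.55 to 5.55 in KO. That of the immediate early genes was 6.62 and 6.52 in the older HET mice, 5.09 and 4.29 in the younger and 4.06 to 4.50 in KO. Without the older mice the calls of immediate early genes (−0.45, adjusted p = 0.0783), endothelium (−0.12, 0.152) and proliferation (0.39, 0.0783) ended, and fibroblasts were at −0.67 (0.0271), myeloid markers at −0.29 (0.0119) and ribosomal proteins at 0.50 (0.0079). Without HET amino 1 the calls of endothelium (−0.37, adjusted p = 0.091), proliferation (0.27, 0.18) and ATF4 targets (0.56, 0.0532) ended, and immediate early genes were at −0.69. Without HET amino 2 the ribosomal call ended (0.21, adjusted p = 0.0887), ATF4 targets were at 0.28 and fatty acid oxidation was at 0.37. Without HET hydroxy 1 immediate early genes were at −0.52 and endothelium at −0.35. Without HET hydroxy 2 the calls of ribosomal proteins (0.19, adjusted p = 0.101), proliferation (0.14, 0.124) and ATF4 targets (0.30, 0.0705) ended, and immediate early genes were at −1.66. Without KO amino 1 the calls of ribosomal proteins (0.24, adjusted p = 0.0984), proliferation (0.13, 0.244) and ATF4 targets (0.41, 0.0984) ended. Without KO hydroxy 2 the same lists ended, at 0.08 for ribosomal proteins (adjusted p = 0.359), 0.03 for proliferation (0.371) and 0.23 for ATF4 targets (0.111). Without KO hydroxy 1 proliferation was at 0.47, ribosomal proteins at 0.51 and myeloid markers at −0.30. In other settings the calls of ribosomal proteins (0.36, adjusted p = 0.0837), proliferation (0.13) and ATF4 targets (0.178) ended at a mean of at least 5 CPM, that of ATF4 targets with library weights (0.0514) and that of ribosomal proteins without the Fabp6 libraries (0.21, 0.0768). At the preset correlation the interferon list passed in 26 of 26 settings, with a median of 1.23 to 2.16, and with an estimated correlation it did not pass (adjusted p = 0.958).

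KO against WT and KO against HET share the KO libraries, so they share their chance values. Across genes their log2 changes correlated at r = 0.742 (mean 0.499, at most 0.520 in 100 simulated draws of unchanged groups). The covariance was 0.150 (mean 0.0397, at most 0.0431). With the KO libraries split by complex, r was 0.410 and 0.457 and the covariance 0.0855 and 0.134. H2-Q10, Oas2 (3.29 in KO against HET), Oas1b (1.81) and Krba1 (−1.69) passed in both, with the same sign. Independent lists would share 0.103 genes up and 0.0340 down, ignoring the shared KO libraries, and the draws 0. The draws may lack correlation between genes, so neither measures chance.

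HET against WT compares carriers of 1 intact copy with mice that have both. Myeloid cell markers rose as a list in HET (0.45, 17 of 17 above 0, adjusted p = 4.02e-04, and adjusted p = 0.954 with an estimated correlation), with 0 members over all genes and 6 adjusted over the list alone, such as Csf1r (0.86), Itgax (0.91), Fcgr1 (0.72) and Cx3cr1 (0.75). The mean level of the myeloid list gave an exact p of 0.0286 and an adjusted exact p of 0.781 over the 41 lists. Immediate early genes rose as a list (1.07, adjusted p = 0.00305, and adjusted p = 0.954 with an estimated correlation), with Egr1 at 3.36 and 0 members past the threshold, and Egr1 was highest in the 2 older HET mice (874 and 657 CPM). Proliferation genes (0.34, adjusted p = 0.0283) and endothelial markers (0.48, 0.0426, with Flt1 past the threshold adjusted over the list alone) rose as lists, each with an adjusted p of 0.954 with an estimated correlation. Adipocyte markers (−0.70, adjusted p = 0.00566) and enterocyte markers (−0.31, 0.00566) fell as lists. These 2 lists also had an adjusted p of 0.954 with an estimated correlation. Limma called 0 genes, with 2137 at an unadjusted p under 0.05. The smallest p belonged to Rpl3 (chromosome 15, 80077781 to 80083406), with 4.49 ± 1.86 CPM in HET and 0.334 ± 0.0924 in WT (1.99, SE 0.22, adjusted p = 0.0732), and to the antiviral deaminase gene Apobec3 (chromosome 15, 79892408 to 79908429), with 18.7 ± 5.40 and 3.12 ± 0.957 CPM (2.25, SE 0.28, adjusted p = 0.0858). KO held 0.506 ± 0.207 CPM of Rpl3 and 4.51 ± 1.24 of Apobec3 (SD, n = 4). Rpl3 encodes a ribosomal protein with many pseudogene copies, so its reads are uncertain. Cbx7 (2.25), Cib1 (−0.85), Angptl4 (−1.85), Smdt1 (−0.90), Lgals3 (−0.94), Crip1 (−1.56), Dmp1 (1.40) and Ebpl (−0.69) followed and did not pass. Mt1 (0.07, adjusted p = 0.972, and −0.05 with quantile normalization) and Mt2 (0.29, 0.834) did not pass.

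Without HET amino 1, 93 genes passed in HET against WT, 18 higher and 75 lower, and without both older HET mice 2 passed. Without both, the calls of immediate early genes (0.19, adjusted p = 0.124), enterocyte markers (0.09, 0.97) and endothelial markers (−0.02, 0.972) ended and adipocyte markers were at −1.61. The adipocyte call ended without HET amino 2 (−0.20, adjusted p = 0.0721) or HET hydroxy 2 (−0.21, 0.0672), and was −1.13 without HET amino 1 and −1.10 without HET hydroxy 1. The enterocyte call ended without HET amino 1 (−0.08, adjusted p = 0.222), HET hydroxy 1 (−0.18, 0.233) or WT amino 1 (−0.27, 0.0781), and was −0.20 without WT hydroxy 1. The proliferation call ended without HET amino 2 (0.32, adjusted p = 0.0968), WT amino 1 (0.20, 0.278) or WT hydroxy 2 (0.31, 0.106). The endothelial call ended without HET amino 1 (0.24, adjusted p = 0.512), HET hydroxy 1 (0.22, 0.158), WT amino 2 (0.43, 0.131) or WT hydroxy 1 (0.37, 0.071), and was 0.74 without HET amino 2 or HET hydroxy 2. Immediate early genes were at 0.65 without HET amino 1, 0.43 without HET hydroxy 1 and 1.70 without HET hydroxy 2, and myeloid markers were at 0.29 without WT amino 1. In other settings the enterocyte call ended with quantile normalization (−0.22, adjusted p = 0.325), the endothelial call with no trend (0.0538) and the proliferation call with the clock score (0.33, 0.0573) or the smooth muscle score (0.38, 0.128). Adipocyte markers were at −0.21 without the Fabp6 libraries and at −0.46 with the smooth muscle score.

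**Figure D5:**
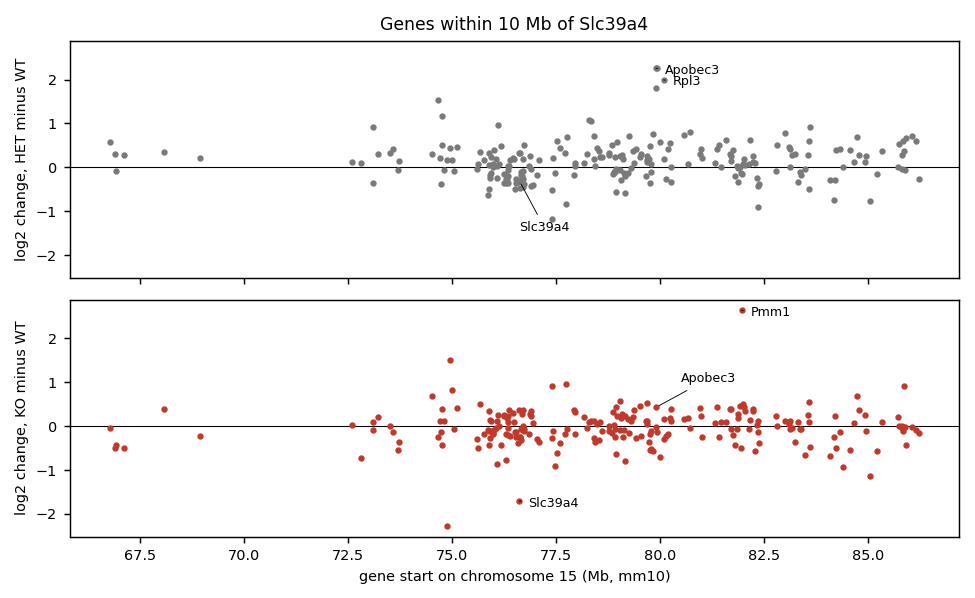
Log2 change (vertical axes) of each tested gene within 10 Mb of Slc39a4 against its start on chromosome 15 in Mb, build mm10 (horizontal axis), for HET minus WT (top) and KO minus WT (bottom), with 1 point per gene and a line at 0. Apobec3 and Rpl3 stand at 2.25 and 1.99 in HET, and Pmm1 at 2.64 in KO.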

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

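The settings without the Fabp6 libraries or with the smooth muscle score were chosen only after the results were seen, and no other test in this part was. In 237 groups of 4 libraries, 1 library stood apart from the other 3 in 7, where chance gives about 1 in 20, or 11.85, and 4 of the 7 were in HET amino 2. In HET, that library held 55.5 CPM of Noct (28.7 to 30.2 in the other HET libraries), 3.99 CPM of H2-Q10 (4.73 to 4.85), 7.27 CPM of Rpl3 (3.38 to 3.65) and 63.0 CPM of Hspa12a (14.7 to 15.6). In KO, Cystm1 was at 27.2 CPM in KO hydroxy 2 (36.2 to 38.3 in the others), Pmm1 at 37.5 CPM in KO amino 1 (78.9 to 87.1) and Dmp1 at 0.600 CPM in KO hydroxy 1 (1.67 to 1.93).

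In 7 lists the effect of the complex differed between KO and WT, each with an adjusted p of 0.866 with an estimated correlation. Proliferation genes differed by 0.79 (adjusted p = 5.77e-09), with 1.26 without KO hydroxy 1, 0.35 without KO hydroxy 2 and 0.49 without WT amino 2. B cell and plasma cell markers differed by 1.75 (adjusted p = 2.08e-08), and ATF4 targets by 0.68 (adjusted p = 0.00166), with 0.37 without KO hydroxy 2 and 0.34 without WT hydroxy 1. Ribosomal protein genes differed by 0.44 (adjusted p = 7.76e-04), a call that ended without KO hydroxy 2 (0.07, 0.202), with 0.88 without KO hydroxy 1, 0.75 without WT amino 1 and 0.26 without WT amino 2. Fibroblast markers differed by −0.57 (adjusted p = 0.00823), which ended without KO hydroxy 1 (−0.12, 0.248) or WT hydroxy 2 (−0.20, 0.11) and was −1.03 without KO hydroxy 2. Tuft cell markers differed by −0.58 (adjusted p = 0.0443), which ended without KO amino 2 (−0.26, 0.598), KO hydroxy 1 (−0.52, 0.128), WT amino 1 (−0.58, 0.068) or WT hydroxy 2 (−0.31, 0.262), with −0.99 without KO amino 1 and −0.9999 without WT hydroxy 1. Sex-linked genes differed by 1.84 (adjusted p = 0.0454), which reversed without KO amino 1 (−0.23, 0.563), ended without HET amino 1 (0.0772), HET amino 2 (0.0765), KO hydroxy 1 (0.215) or WT amino 1 (1.76, 0.14), and was 4.04 without KO amino 2. In other settings it ended with no filter (1.58, 0.23), a mean of at least 5 CPM (1.58, 0.319), a pseudocount of 5 (0.88, 0.0879), quantile normalization (0.0955), no trend (0.0533), library weights (0.139) or the smooth muscle score (0.0698), and without the Fabp6 libraries (0.0808). The tuft cell call ended at a mean of at least 5 CPM (−0.63, 0.114), where B cell markers were at 0.61. With the smooth muscle score fibroblast markers were at −0.37 and tuft cell markers at −0.39.

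In 3 lists the effect of the complex differed between HET and WT, each with an adjusted p of 0.0263 and an adjusted p of 0.9997 with an estimated correlation. Enterocyte markers differed by 0.30, which ended without HET amino 1 (−0.09, adjusted p = 0.645), HET hydroxy 2 (0.12, 0.983), WT amino 1 (0.08, 0.408) or WT hydroxy 2 (0.30, 0.198), with 0.51 without HET amino 2, 0.54 without HET hydroxy 1 and 0.47 without WT amino 2. Genes of the unfolded protein response differed by 0.30, which reversed without HET amino 1 (−0.15, adjusted p = 0.422) and ended without HET hydroxy 2 (0.26, 0.318), WT amino 2 (−0.02, 0.635) or WT hydroxy 2 (0.04, 0.543). Without HET amino 2 they were at 0.70, without WT amino 1 at 0.61 and without WT hydroxy 1 at 0.47. Interferon genes differed by −0.67, which ended without HET amino 2 (−0.26, adjusted p = 0.977, with a test of the opposite sign), HET hydroxy 1 (−0.77, 0.351), WT amino 1 (−0.08, 0.931) or WT hydroxy 1 (−0.37, 0.601). Without HET amino 1 they were at −1.24, without WT amino 2 at −1.33 and without WT hydroxy 2 at −1.05. In other settings the interferon call ended with a pseudocount of 5 (−0.53, adjusted p = 0.0547) or quantile normalization (−0.52, 0.099) and reversed without the Fabp6 libraries (0.13, 0.164). The enterocyte call ended with quantile normalization (0.11, adjusted p = 0.505), TMM factors (0.133), age as a covariate (0.116), a mean of at least 5 CPM (0.0541) or the smooth muscle score (0.168). The call of the unfolded protein response ended with quantile normalization (adjusted p = 0.099), TMM factors (0.0572), age (0.116), a mean of at least 5 CPM (0.0568) or the smooth muscle score (0.168). Without the Fabp6 libraries enterocyte markers were at 0.65 and the unfolded protein response at 0.92.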

How the results depend on the processing

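The settings without the older HET mice, the Fabp6 libraries or Slc39a4 in the zinc lists, or with a clock or smooth muscle score, were chosen after the results were seen, the others before. Without counting left-out libraries, 364 values of the main results held, 65 moved, 8 became stronger, 2 weaker and 6 reversed. With libraries left out 288 held, 55 moved, 8 weakened and 9 reversed. Of the single genes and lists, 2234 held, 173 weakened, 71 strengthened and 1 reversed, and with libraries left out 1791 held, 258 weakened, 9 strengthened and 6 reversed. The interferon list in KO against WT kept its direction and call in 26 of 26 settings at the preset correlation, and lost the call with an estimated correlation (adjusted p = 0.651). The zinc-responsive list in KO against WT lost its call without its member Slc39a4 (−0.20, adjusted p = 0.165). Where a result changed, the cause was not tested.

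For KO against WT (4 genes) the count was 1 with a pseudocount of 0.1, 10 with 5, 1 at a mean of 5 CPM, 23 with quantile normalization, 1 with TMM, 32 with library weights, 23 with age, 13 in the additive model, 51 at a threshold of 0.10, 1 without the Fabp6 libraries, 102 with the clock score and 290 with the smooth muscle score. For HET against WT (0) it was 1 without a filter, without a trend or with weights, 3 with age, 2 in the additive model, at 0.10 or without the older HET mice, 3 with the clock score and 1382 with the smooth muscle score. For KO against HET (957) it was 1651 with quantile normalization, 602 without a trend, 280 with weights, 1646 with age, 10 with only the groups compared, 2278 at 0.10, 448 without the older HET mice, 2 without the Fabp6 libraries, 1961 with the clock score and 3946 with the smooth muscle score. For the complex in KO (0) it was 2 without a filter, 1 with only the groups compared and 6 with the smooth muscle score, and for the difference between KO and WT (0) 1 without a filter.

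Slc39a4 in KO against WT (−1.71, adjusted p = 0.0736, up to 0.382 over all settings) passed with quantile normalization (−1.74, 0.046), weights (−1.71, 0.0357), age (−1.69, 0.0133), only the groups compared (−1.71, 0.0302), a threshold of 0.10 (−1.71), without the older HET mice (−1.71, 0.0334), with the clock score (−1.74, 0.0221) and with the smooth muscle score (−1.89, 0.00631). In KO against HET it did not pass with only the groups compared (−1.40, 0.0784) or without the Fabp6 libraries (−1.13, 0.0675). Reversed values were Mt2 in KO against WT (0.0056 with a pseudocount of 5 and 0.0097 with the smooth muscle score), Slc39a4 in HET against WT without the older HET mice (0.18), Mt1 in HET against WT (−0.051 with quantile normalization, −0.38 without the Fabp6 libraries), Mt2 in HET against WT (−0.24 without the Fabp6 libraries) and the interferon list in the difference between HET and WT (0.13 without the Fabp6 libraries).

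The number of lists called was 0 in all 9 comparisons with an estimated correlation. Without the Fabp6 libraries it was 14 for the complex over all genotypes, 16 in WT, 16 in HET, 11 for HET against WT, 15 for the difference between KO and WT and 17 for that between HET and WT. With the clock score it was 18, 18 in WT, 7 in HET, 14 and 13 for the differences. With the smooth muscle score it was 9 in WT, 7 in HET, 11 for HET against WT and 12 for KO and WT. In HET it was 6 with a pseudocount of 0.1, 8 with age and 7 at 0.10, and at 0.10 the difference between KO and WT had 11. The difference between HET and WT had 0 with quantile normalization and 1 with TMM.

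Leaving out each library gave 1 to 14 genes for KO against WT, 0 to 93 for HET against WT, 1 to 1393 for KO against HET, 0 to 4 for the complex in KO, 0 to 2 over all genotypes, 0 to 6 in HET and 0 to 2 for the difference between KO and WT. Log2 changes ranged from −0.16 to 0.29 for Mt1 and −0.045 to 0.62 for Mt2 in HET against WT, −0.88 to 0.072 for Mt2 in KO against HET, −0.59 to 0.36 for Mt2 in KO against WT and −1.67 to −1.13 for Slc39a4 in KO against HET. List medians ranged from 0.13 to 1.92 for Paneth cells in HET, −0.39 to 0.071 for T cells over all genotypes, −1.33 to −0.078 for interferon (−0.26 where its test reversed) and −0.15 to 0.70 for the unfolded protein response in the difference between HET and WT, −0.23 to 4.04 for sex-linked genes in that between KO and WT, and −0.011 to 4.24 in KO. Lists called numbered 9 to 19 for the complex over all genotypes, 5 to 16 in WT, 3 to 16 in HET, 9 to 13 in KO, 11 to 17 for KO against WT, 4 to 10 for HET against WT, 6 to 11 for KO against HET, 7 to 16 for the difference between KO and WT and 3 to 17 for that between HET and WT. The planned tests for counts were not run, since the values are CPM. At 3 reads, or 0.0773 to 0.115 CPM, genes with low values rest on few reads.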

Other observations

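The tests here on cell types, clock, zinc level, chromosome 15 and sex labels were chosen only after the results were seen, and the counts over other splits before. Beside Slc39a4 (76.61 Mb), chromosome 15 held 4 neighbouring genes at 79.9 to 80.1 Mb that were higher in each HET library than in any WT or KO library, singled out after their values were seen. Apobec3 stood at 13.7 to 26.0 CPM in HET, 1.80 to 4.08 in WT and 3.04 to 6.08 in KO, and Cbx7, a Polycomb protein gene, at 12.8 to 20.1, 1.57 to 5.51 and 1.17 to 4.46. Rpl3 stood at 3.38 to 7.27 CPM in HET. D730005E14Rik, which overlaps Apobec3 and so may share its reads, stood at 1.33 to 4.36 CPM in HET and at the floor elsewhere except 0.0657 in WT hydroxy 2. In KO against WT, Pmm1 (81.95 Mb) was at 2.64, 2010109I03Rik (74.88 Mb) at −2.27 and Ly6e (74.96 Mb) at 1.51 (log2). The 4 genes had a median log2 change of 2.12 in HET (1.82 to 2.25) and 0.0725 in KO, but were picked for standing above KO. Since the 4 were so picked, their KO changes (at most 0.427) cannot decide on a segment shared with KO. Rpl3, Apobec3 and Cbx7 also ranked high by p in HET against WT.

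A candidate explanation for the 4 genes is a segment around Slc39a4 that differs in the HET animals. Among the other genes within 10 Mb, 20 of 226 (8.85%) had an unadjusted p under 0.01 in HET against WT, and 598 of 13770 elsewhere (4.34%), with a one-sided Fisher exact p of 0.00247, while for KO against WT it was 9 of 226 (3.98%) with an exact p of 0.161. A share as high as in HET was found in 21 of 933 windows of this width around other genes (2.25%), and genes in a window are not independent. Sequence variants are not analysed here, so the origin of such a segment, and whether KO animals carry part of it, stays open.

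The interferon genes were higher in KO than in WT by a median of 1.67. More leukocytes in KO would raise their markers, and the 44 markers of myeloid, T and B cells had a median of 0.0133 (quartiles −0.0986 to 0.280). Time of day as the whole cause would remove the shift, and with a clock score in the model the median was 1.31. With 0 KO libraries at 15 ppm zinc, the genotype and the zinc level cannot be told apart. A change in the knockout or in its diet, or an infection of these animals, stays open, and the last was not tested.

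For the libraries labelled KO amino 1 and 2, an exchange of the sex labels between them is consistent with 244 CPM of Xist in the first and Y-linked reads in the second. A single wrong label would leave the library labelled female without Y-linked reads, and it held 32.2 CPM of Ddx3y. No biological explanation was tested. The exchange may also have moved the ages of these mice, 198 and 228 days, and it leaves the groups as they are.

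Other splits of the same libraries give a measure of chance. For KO against WT (additive model, 13 genes), 1 of 35 splits, the real one, gave as many, and the highest other gave 1. That is the smallest share that 35 splits allow, in 1 of several comparisons, so chance is less likely but not excluded. At an unadjusted p under 0.05 (1376 genes) 2 of 35 splits, the real one included, gave as many. For KO against HET (1247 genes), 1 of 35 gave as many, and the highest other gave 342, with the same limit. At an unadjusted p under 0.05 (4079 genes) 1 of 35 gave as many too. For HET against WT (2 genes), 3 of 35 gave as many, so chance is not excluded, and the highest other gave 986. At an unadjusted p under 0.05 (2195 genes) 6 of 35 gave as many. For hydroxy against amino over all genotypes, limma called 0 genes, so all 100 of the 100 splits drawn from 108 had to give as many and the count decides nothing, and the highest other gave 2569. At an unadjusted p under 0.05 the real split gave 1255 genes, and 22 of the 100 splits, the real one included, gave as many. Splits that call many genes point to a structure of the samples.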
